A study of Mus musculus with 5 samples.

How the data were processed

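The series holds 5 single-cell RNA libraries of adult mouse cardiac interstitial cells, made with droplet-based 3-prime chemistry after enzymatic digestion, removal of cardiomyocytes and flow sorting on surface cKit and DDR2. CD45 was used to part the double-positive cells. The libraries cover 4 sorts: cKit-/DDR2+ (1 library), cKit+/DDR2- (replicates 1 and 2), cKit+/DDR2+/CD45- (1) and cKit+/DDR2+/CD45+ (1).

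Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with Cell Ranger, version not given, and cells were filtered and normalised with Seurat 4.0.4. The deposited tables give gene symbols only and hold, per cell, the natural log of 1 plus UMIs scaled to 10000. The number of UMIs of each cell was recovered from these values. All values came back as whole counts within a tolerance of 0.01 (100% in each library), and every cell summed to 10000 after back-transformation. Between 13222 and 16326 genes are listed per library, and a gene not listed in a library was treated as 0 there. Upstream filters show in the values. Between 12 and 77 genes per library are listed with UMIs in 1 cell and between 444 and 549 in 3 cells, which points to a filter on genes seen in fewer than 3 cells, so that a gene not listed may have had UMIs in up to 2 cells. No cell exceeds 10.0% mitochondrial UMIs. A filter of at least 200 genes, 500 UMIs and at most 15% mitochondrial UMIs therefore removed a single cell, from cKit+/DDR2+/CD45+.

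Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Cells of all libraries were log-normalised to 10000, reduced over 2000 variable genes to 30 principal components, joined by 15 neighbours and clustered with the Leiden method at resolution 1.0 and seed 1. No batch integration was applied, and Kit, Ddr2 and Ptprc were kept out of the variable genes. Clusters were named from 21 marker lists (126 genes): a class needed at least 3 markers detected in 20.0% of cells and 2-fold above the other cells. The 10 leading genes of a cluster, seen in at least 25.0% of its cells, were not to hold as many or more markers of another class. This last rule was revised after the clusters were seen, by comparing leading genes with cells of the same library, while the marker lists were not changed. Clusters whose median UMIs lay below 1/3 of the library median are described as low in depth. The suffix "-like" marks classes named from RNA.

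UMIs were summed over the cells of a library, or of a class in a library with at least 50 cells, and scaled to CPM. Fold differences are log2 ratios after adding 1 CPM, for genes with at least 50 CPM in 1 group. cKit+/DDR2- is the mean of its 2 libraries, and its genes count as 2-fold apart only where both libraries are at least 2-fold apart on the same side. The 4 comparisons were cKit+/DDR2+/CD45- minus cKit-/DDR2+, cKit+/DDR2+/CD45- minus cKit+/DDR2-, cKit+/DDR2+/CD45+ minus cKit+/DDR2+/CD45-, and cKit+/DDR2- minus cKit-/DDR2+. In macrophage-like cells, cKit+/DDR2+/CD45+ was compared with cKit+/DDR2- replicate 2. No significance test was run, and no p-value is given. Intervals of log2 ratios are those of the ratio without the added CPM. Where both cKit+/DDR2- libraries enter, the range given is that of the log2 ratios with each of the 2 libraries, and not an interval. Where a gene is listed in a library but had 0 UMIs in the cells compared, the ratio was taken against a floor of 3 counts. Where it is not listed, the ratio is given for 2 hidden cells, at the highest mean UMIs of its positive cells in any library and at its highest UMIs in any cell.

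Genes were named by a rule: Kit, Ddr2 and Ptprc, the 8 largest differences each way with at least 50 CPM and 20 UMIs in the higher group, and up to 4 members of each list. Mitochondrial, ribosomal protein, haemoglobin, Xist, Y-linked and predicted genes were left out of the 8. The text gives part of the genes so named. A further 2 of them are not reported here and were left out of the tables of named genes and of alternatives, and no others took their place. There were 20 lists (228 genes): sort targets, fibrillar matrix, basement membrane, fibroblast activation, contractile, progenitor-like fibroblast, senescence and secretory phenotype, proliferation, ERK feedback, immediate early and dissociation, mesenchymal transition factors, pan-immune, MHC class II, interferon response, complement and chemokines, growth factors, glycolysis, and arterial, capillary and venous endothelial genes. A list needed at least 3 measured genes. Its median was placed among 10000 random lists of the same size matched on expression, and called outside their middle 95%. The list symbols Ccn1 and Ccn2 appear in the tables as Cyr61 and Ctgf. Sorts, comparisons, lists, the rule for naming genes and the first set of alternatives were set before the data were examined, and the cluster naming rule and the added alternatives were not.

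For shares of cells with a gene, cells were thinned to 1000 UMIs and shallower cells left out, which kept 2226 cells of cKit-/DDR2+, 430 and 2969 of cKit+/DDR2-, 1277 of cKit+/DDR2+/CD45- and 3595 of cKit+/DDR2+/CD45+. Proliferating cells were those with UMIs of at least 2 of 8 genes (Mki67, Top2a, Birc5, Ube2c, Cdk1, Ccnb1, Ccna2, Cenpf). With 1 library per sort, depth sets the precision of a count and not that of a sort. The procedure was tested on simulated data with the same depths. Counts were Poisson draws from 1 profile shared by the libraries, apart from the set folds. They hold no variation between libraries and no correlation between genes, so that error rates on the real libraries were not tested. Between the real cKit+/DDR2- libraries, 309 of 3457 genes lay 2-fold or more apart. Genes set 3-fold apart were called in 99% to 100% of cases, genes set 1.5-fold apart in 0% to 2%, and 0 unchanged genes were called. Of 133 list medians on the simulated data, 9 (6.77%) lay outside the middle 95% of random lists. The intervals held the true ratio for 94.7% to 95.3% of genes.

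The first set of alternatives held factors of the trimmed mean of M-values (TMM), totals without mitochondrial, ribosomal and haemoglobin genes, the mean over cells in place of the sum, 10 CPM added, minima of 10 and 200 CPM, no cell filter, a filter of 1000 genes and 5% mitochondrial UMIs, removal of the cells with the highest doublet scores (0.8% per 1000 cells), resolutions 0.5 and 2, classes from marker genes of single cells, thinning to 2000 UMIs or none, and leaving out each cKit+/DDR2- replicate. The TMM factors were computed in numpy and not with edgeR. Chosen after seeing the data were leaving out cells with shared barcodes, totals without Gm42418, AY036118 and Lars2, a minimum of 30 cells per class, the largest shared cluster of a class, and endocardial-like cells as a class of their own.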

Results

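Cardiac interstitial cells of adult mice were sorted on surface cKit, DDR2 and, in the double-positive cells, CD45, and their RNA was counted cell by cell in 5 droplet libraries. cKit is a receptor tyrosine kinase (gene Kit) carried by several blood and endothelial lineages, DDR2 is a collagen receptor of fibroblasts (gene Ddr2), and CD45 is the phosphatase common to leukocytes (gene Ptprc). The 4 sorts were cKit-/DDR2+ with 1 library, cKit+/DDR2- with 2 libraries, cKit+/DDR2+/CD45- with 1 library and cKit+/DDR2+/CD45+ with 1 library. The cKit-/DDR2+ library held 2280 cells and 20774882 UMIs (unique molecular identifiers, 1 per captured transcript). The cKit+/DDR2- libraries held 436 cells with 4047326 UMIs in replicate 1 and 3020 cells with 29542372 UMIs in replicate 2. The cKit+/DDR2+/CD45- library held 1327 cells and 11942544 UMIs, and the cKit+/DDR2+/CD45+ library 3897 cells and 44847282 UMIs. Median UMIs per cell lay between 7529 in cKit-/DDR2+ and 10973 in cKit+/DDR2+/CD45+.

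With 1 library in 3 of the 4 sorts, no test between sorts was run, and every fold describes these libraries. Expression is given as CPM, the counts summed over cells and scaled to a common total, and folds as log2 of the ratio after adding 1 CPM. Intervals are 95% Poisson intervals for CPM, exact Clopper-Pearson intervals for shares of cells and exact intervals for log2 ratios between single libraries. They cover counting error only. Where both cKit+/DDR2- libraries are pooled, the range beside a log2 ratio runs over these 2 libraries and is not a 95% interval. The 2 cKit+/DDR2- libraries set the yardstick: of 3457 genes with at least 50 CPM in either, 309 (8.94%) lay 2-fold or more apart. In endocardial-like cells of the same libraries the count was 79 of 3261 genes. The 2 libraries differ in shares of cell classes and lie on either side of a split in Xist levels described below. These counts therefore do not measure replicate noise alone.

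Ptprc mRNA followed the CD45 gate, while Kit mRNA departed from its gate in cKit+/DDR2+/CD45+ and Ddr2 mRNA in both double-positive sorts. The gates were set on surface protein, which was not measured here, and mRNA can be low where protein is present. The cause of these departures was not tested for Kit. Kit reached 22.6 CPM in cKit+/DDR2+/CD45-, 35.6 and 21.7 CPM in cKit+/DDR2- replicates 1 and 2, and 4.67 CPM (3.79 to 5.70) in cKit-/DDR2+. It was lowest in a sort gated cKit+, with 3.48 CPM (2.95 to 4.07) in cKit+/DDR2+/CD45+. Ddr2 reached 106 CPM (101 to 110) in cKit-/DDR2+ but 15.3 CPM (13.2 to 17.7) in cKit+/DDR2+/CD45-, beside 3.21 and 13.8 CPM in the cKit+/DDR2- libraries, and 1.36 CPM in cKit+/DDR2+/CD45+. Ptprc reached 318 CPM in cKit+/DDR2+/CD45+. It is not listed for cKit+/DDR2+/CD45- and was set to 0 there. The table of that library lists 22 genes seen in 1 cell, 96 in 2 cells and 512 in 3 cells, as after a filter that drops genes seen in fewer than 3 cells, so that a gene not listed may have had UMIs in up to 2 cells. For Ptprc, 2 cells at the highest mean of its positive cells in any library (5.26 UMIs) would give 0.881 CPM, and 2 cells at its highest UMIs in any cell (24) 4.02 CPM. It stood at 37.1 and 126 CPM in the cKit+/DDR2- libraries and 5.82 CPM in cKit-/DDR2+.

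At an equal depth of 1000 UMIs per cell, Kit was seen in 2.51% of cells of cKit+/DDR2+/CD45- (1.72 to 3.52), in 2.79% and 1.35% in the cKit+/DDR2- libraries, in 0.494% in cKit-/DDR2+ and in 0.417% in cKit+/DDR2+/CD45+. Ddr2 was seen in 6.15% of cells of cKit-/DDR2+ (5.19 to 7.23) and 0.940% of cells of cKit+/DDR2+/CD45- (0.486 to 1.64). As background at this depth, Kit was seen in 0 of 908 fibroblast-like cells of cKit-/DDR2+, with a floor of 3 cells at 0.330%, and Ddr2 in 0.0308% of macrophage-like cells of cKit+/DDR2+/CD45+. At full depth Ddr2 was seen in 36.1% of cells of cKit-/DDR2+ and 7.08% of cells of cKit+/DDR2+/CD45-, and Kit in 3.46% and 10.3%, beside Kit in 0.991% of those fibroblast-like cells (median 14242 UMIs) and Ddr2 in 0.478% of those macrophage-like cells (median 11073 UMIs).

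**Figure D1:**
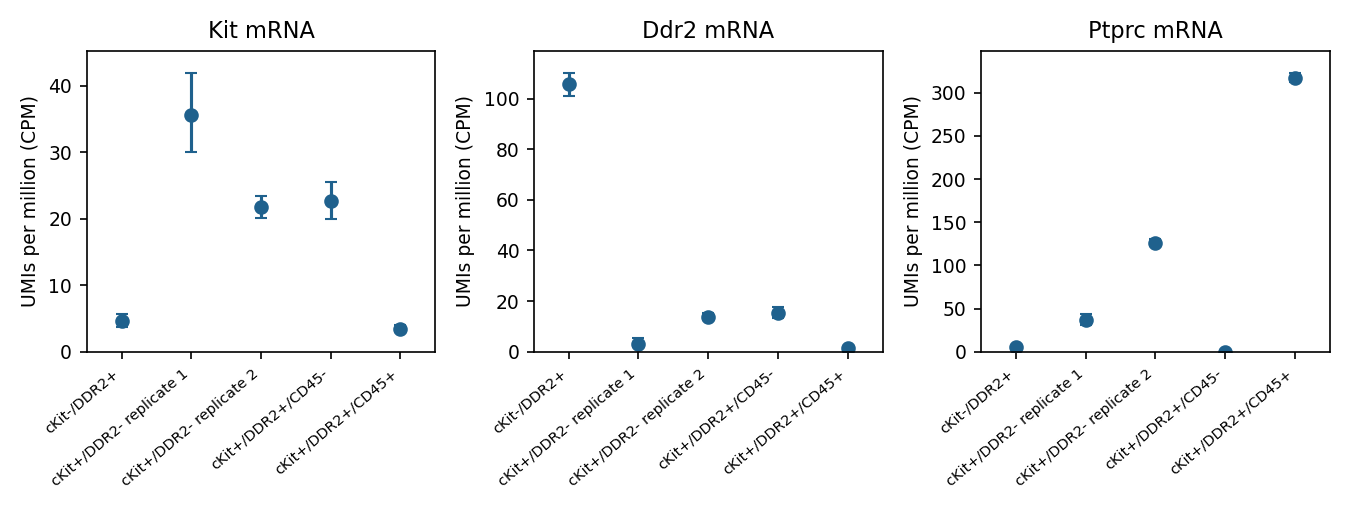
CPM of Kit, Ddr2 and Ptprc in each library, with 95% Poisson intervals. Ddr2 stands at 106 CPM in cKit-/DDR2+ and 15.3 CPM in cKit+/DDR2+/CD45-, and Ptprc at 318 CPM in cKit+/DDR2+/CD45+.

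Cell classes were named from marker genes of clusters. Fibroblast-like cells (Gsn, Dcn, Col1a1) made up 39.8% of cKit-/DDR2+ (37.8 to 41.9) but 3.01% of cKit+/DDR2+/CD45- (40 cells, 2.16 to 4.08). They made up 0.229% and 4.97% of the cKit+/DDR2- libraries and 0.539% of cKit+/DDR2+/CD45+. Endothelial-like cells of any kind formed 94.5% of cKit+/DDR2+/CD45-, 92.0% and 65.3% of the cKit+/DDR2- libraries, and 54.6% of cKit-/DDR2+. In cKit+/DDR2+/CD45- these were blood endothelial-like cells (Cdh5, Fabp4, Cd36; 47.9%), endocardial-like cells (Npr3, Vwf, Cytl1; 40.6%) and lymphatic endothelial-like cells (Ccl21a, Mmrn1, Prox1; 5.95%). Endocardial-like cells formed 41.1% and 46.9% of the cKit+/DDR2- libraries and 2.46% of cKit-/DDR2+, whose endothelial-like cells were nearly all of the blood type (51.8%). Lymphatic endothelial-like cells formed 21.3% and 8.05% of the cKit+/DDR2- libraries and 0.263% of cKit-/DDR2+.

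Immune-like cells followed the CD45 gate. Macrophage-like cells (C1qa, Csf1r, Adgre1) formed 85.8% of cKit+/DDR2+/CD45+ (84.7 to 86.9), 5.05% and 17.5% of the cKit+/DDR2- libraries, 1.10% of cKit-/DDR2+ and 0.301% of cKit+/DDR2+/CD45- (4 cells). Dendritic-like cells (Xcr1, Flt3) formed 7.72% of cKit+/DDR2- replicate 2 and 0.688% of replicate 1. Pericyte-like cells (Kcnj8, Vtn, Abcc9) formed 2.72% of cKit-/DDR2+ and 1.21% of cKit+/DDR2+/CD45-. Clusters left without a name held between 0.603% and 3.41% of a library.

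**Figure D2:**
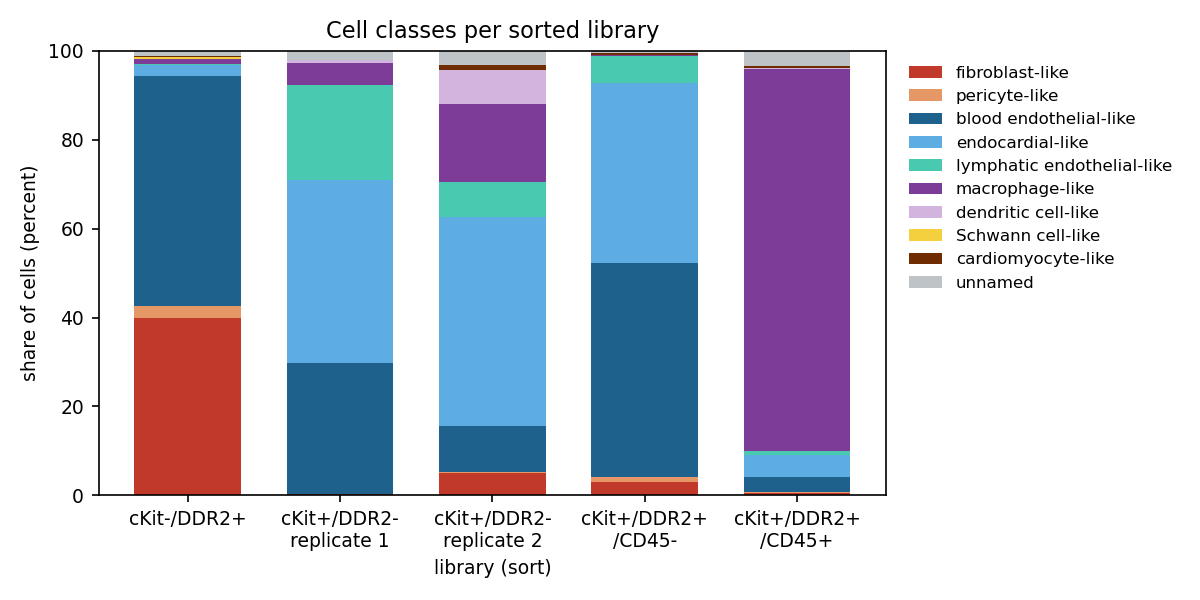
Percent of cells of each library in each cell class, as stacked bars. Fibroblast-like cells fill 39.8% of cKit-/DDR2+ and 3.01% of cKit+/DDR2+/CD45-, and macrophage-like cells fill 85.8% of cKit+/DDR2+/CD45+.

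The libraries also split in a way that the sorts do not set. Xist stood at 496 CPM in cKit+/DDR2- replicate 2 and 757 CPM in cKit+/DDR2+/CD45-, and at 0.0669 CPM in cKit+/DDR2+/CD45+. It is not listed for cKit-/DDR2+ and cKit+/DDR2- replicate 1. In these 3 libraries the Y-linked gene Ddx3y stood at 98.6 CPM (cKit-/DDR2+), 80.3 CPM (cKit+/DDR2- replicate 1) and 58.8 CPM (cKit+/DDR2+/CD45+). The model Gm42418 took 9.09% and 10.6% of UMIs in the libraries with high Xist, cKit+/DDR2- replicate 2 and cKit+/DDR2+/CD45-. It took 0.980% to 1.39% in the others, and Lars2 behaved alike (2340 and 2814 CPM against 290, 567 and 300.3 CPM). The comparisons of cKit+/DDR2+/CD45- with cKit-/DDR2+ and with cKit+/DDR2+/CD45+ cross this split and have no library pair within it. Because Xist and Ddx3y are sex-linked genes, folds across it cannot be parted from the sex of the animals or from other differences between libraries. Neither was tested. For the 2 comparisons with cKit+/DDR2-, gene counts and some medians and folds within the split are given beside the pooled ones, and all other values are pooled over the replicates.

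The comparison of cKit+/DDR2+/CD45- with cKit-/DDR2+ asks how DDR2-sorted cells with surface cKit differ from those without it. Over whole libraries, the fibrillar matrix list, with the collagens that carry the tension of the heart wall, was lower in cKit+/DDR2+/CD45- (-2.41), as were the lists of complement and chemokine genes and of progenitor-like fibroblast genes, beside a share of fibroblast-like cells of 3.01% against 39.8%. Within classes the fibrillar matrix list was not lower by its test: it was not called in blood endothelial-like cells (-0.37, percentile 5.65) and was high in fibroblast-like cells (0.22, percentile 99.99, 0 of 17 genes at least 2-fold apart), where a minimum of 30 cells was chosen after seeing the data. Single genes that were higher included the natriuretic peptide receptor gene Npr3, the trophic factor gene Nrg1, the chemokine gene Ccl21a and the hyaluronan receptor gene Lyve1. Of 3583 genes with at least 50 CPM, 267 were at least 2-fold higher and 350 at least 2-fold lower.

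Among the higher genes, Ccl21a had 1693 CPM against 7.99 CPM (log2 7.56), H19 446 against 6.79 CPM (5.84), Npr3 1332 against 30.7 CPM (5.39), Nrg1 133 against 1.88 CPM (5.54) and Vwf 1115 against 71.2 CPM (3.95). Mmrn1 (5.70), Reln (5.31) and Lyve1 (5.21), genes of lymphatic endothelium, and the guanylate-binding protein gene Gbp8 (5.40) followed. Bmx (3.85), Cdh11 (3.23), Dpp4 (3.05) and Nr2f2 (2.29) were higher too. Among the lower genes, Col1a1 had 67.6 CPM against 772 CPM (log2 -3.49, -3.62 to -3.41), Col3a1 152 against 1318 CPM (-3.11, -3.18 to -3.04) and Dpep1 16.4 against 566 CPM (-5.02). Cxcl14 (-6.22), Ccl7 (-5.86), Penk (-5.64), Ccl11 (-5.62), Apod (-5.26), Ifi205 (-4.69) and Wisp2 (-4.43) had the lowest ratios. Pi16 (-3.30) and Cd248 (-3.17), genes of progenitor-like adventitial fibroblasts, and Igf1 (-3.11), a growth factor gene, were lower as well. Kit itself was higher (2.06) and Ddr2 lower (-2.71).

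Gene lists fixed beforehand are summarised by the median log2 ratio of their measured members, with its percentile among 10000 random lists of the same size and expression. The fibrillar matrix list had a median of -2.41 over 17 genes and the complement and chemokine list -3.17 over 8 genes, both below every random list. Also low were basement membrane (-1.72, percentile 0.02), progenitor-like fibroblast (-1.40, 0.295), senescence and secretory phenotype (-1.30, 0.02), growth factors (-0.92, 0.58) and immediate early genes (-0.73, 0.06). The last list holds genes that tissue digestion induces, such as Fos (-1.70) and Junb (-1.26). Venous endothelial (1.87, 99.94), MHC class II (1.75, 99.72) and capillary endothelial (0.43, 98.9) lists were high. The lists of fibroblast activation (-0.17), contractile genes (-0.32), ERK feedback (0.07), mesenchymal transition factors (-0.57), interferon response (0.84), glycolysis (-0.19) and arterial endothelial genes (-0.49) lay within the middle 95% of random lists and were not called. The proliferation list had fewer than 3 measured genes here.

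Within blood endothelial-like cells, 636 against 1182 cells, the MHC class II list was higher and the arterial endothelial list lower. Of 3340 genes, 37 were at least 2-fold higher in cKit+/DDR2+/CD45- and 43 lower, fewer than the 284 of 3467 between the cKit+/DDR2- libraries in this class. Those libraries hold only 129 and 312 cells of it and lie on either side of the Xist split. The MHC class II genes, which load peptides for CD4 T cells, were higher: Cd74 at 151 against 9.94 CPM (3.79, 3.54 to 4.33), H2-Aa (3.35) and H2-Ab1 (3.13), with a list median of 3.35 above every random list. The chemokine gene Cxcl9 (3.21) and the interferon-inducible GTPase genes Tgtp2 (2.94) and Iigp1 (478 against 79.5 CPM, 2.57) were higher too, as was Lars2 (2.47). Kit stood at 56.1 against 14.3 CPM (1.90, 1.61 to 2.35) and Ddr2 at 7.67 against 12.5 CPM (-0.64, -1.35 to -0.08). Lower were Gsn (-4.76) and Dcn (-3.79), abundant fibroblast transcripts in a library with 39.8% fibroblast-like cells, the heat shock gene Hsph1 (-2.33), the clock gene Dbp (-1.80), the Notch target Hey1 (-1.75), Igfbp3 (-1.63), Cygb (-1.54) and S100a6 (-1.54). With classes taken from marker genes of single cells, Dcn turned to 1.38 and 386 genes lay 2-fold apart, but that class took in 496 endocardial-like cells of cKit+/DDR2+/CD45- and 39 of cKit-/DDR2+.

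The arterial endothelial list had a median of -1.06 in this class (percentile 0.02), and immediate early genes lay below every random list (-0.63). ERK feedback (0.24, no member called), interferon response (0.38, none) and venous genes (0.35) were high against random lists, and growth factors low (-0.54). ERK feedback turned to -0.37 with classes from single cells, and venous genes to -0.059 with the mean over cells. The class was made up of different clusters in the 2 sorts. A cluster led by Rbp7 and Rgcc held 55.6% of it in cKit-/DDR2+ and 31.8% in cKit+/DDR2+/CD45-, and a cluster with Apln and Nes 5.41% and 35.1%. Within the Rbp7 cluster alone, Cd74 did not differ in this direction (-0.21), and the median of the 3 MHC class II genes was 1.42. Fibroblast-like cells of cKit+/DDR2+/CD45- were too few, at 40, for the planned comparison of at least 50 cells.

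**Figure D3:**
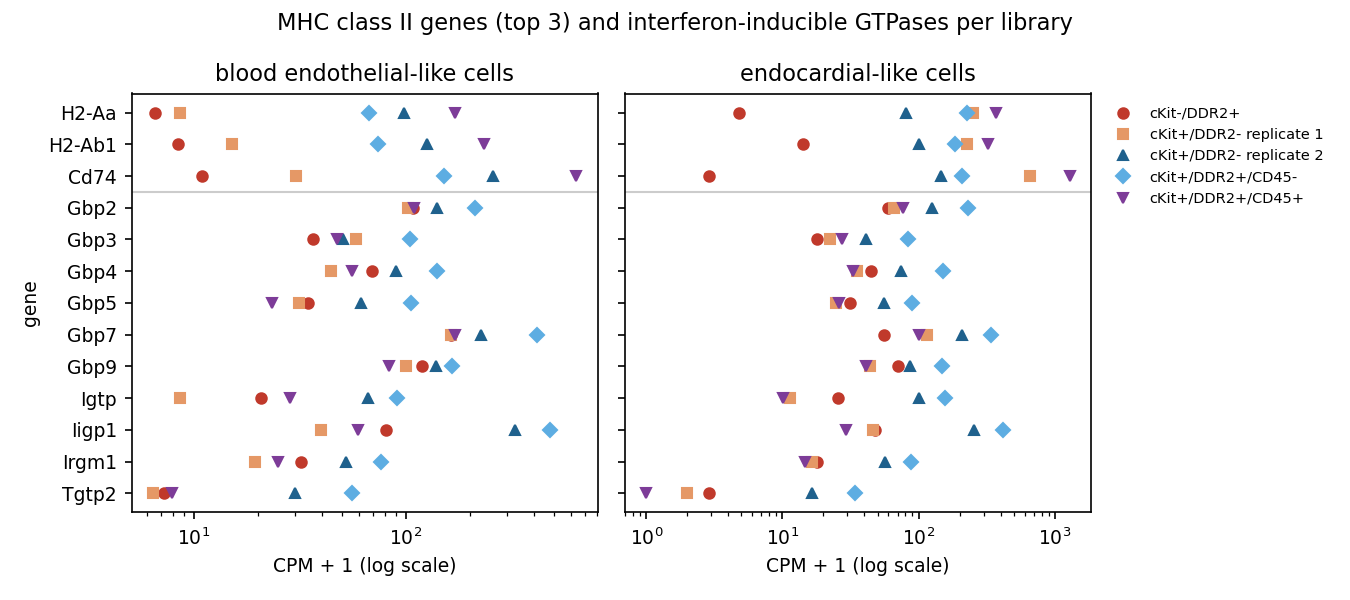
CPM of MHC class II and interferon-inducible GTPase genes in blood endothelial-like and endocardial-like cells of each library, on a log scale with 1 CPM added. In blood endothelial-like cells Iigp1 stands at 478 CPM in cKit+/DDR2+/CD45- and 79.5 CPM in cKit-/DDR2+.

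The comparison of cKit+/DDR2+/CD45- with cKit+/DDR2- asks what surface DDR2 adds among cKit-positive cells. The pan-immune list was lower in cKit+/DDR2+/CD45-, and the CD45 gate was applied to the double-positive cells alone. Single genes that were lower included the cytokine gene Il1b, the chemokine gene Ccl3 and complement C1q genes. The fixed list of complement and chemokine genes, which holds none of these, was high against random lists (0.55, percentile 98.6), with Cxcl12 called among its 3 measured genes, and stood at 0.17 against replicate 2 alone and 1.499 against replicate 1 alone. The capillary endothelial list, with the carbonic anhydrase gene Car4 and the fatty acid transporter gene Cd36, was higher too. It stood beside a share of blood endothelial-like cells of 47.9% against 29.6% and 10.3% in replicates 1 and 2. Of 3344 genes, 31 were at least 2-fold higher and 92 lower against both cKit+/DDR2- libraries. Against replicate 2 alone, which lies on the same side of the Xist split, 347 genes were at least 2-fold apart, and against replicate 1 alone 161, fewer than the 309 between the replicates.

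Ccl3, Rgs1, Il1b and Ptprc are not listed for cKit+/DDR2+/CD45-, against 170, 138, 80.1 and 81.7 CPM in the mean of the cKit+/DDR2- libraries. If 2 cells there held the highest mean UMIs of positive cells, they would be 56.3-fold, 51.0-fold, 33.5-fold and 92.7-fold lower, and 35.5-fold, 35.4-fold, 31.0-fold and 42.1-fold lower than in replicate 1. At the highest UMIs of any cell the folds would be 5.63, 4.17, 2.38 and 20.3. Cxcl2 (-7.80), Ccl4 (-7.39, from 2 UMIs), C1qa (-6.79), C1qc (-6.66) and Csf1r (-6.58) were lower as well, and the pan-immune list had a median of -6.05 over 9 genes. Cd74 stood at 209 against 3870 CPM (-4.21), and the MHC class II list at -3.35. Higher genes included Rgs5 (287 against 57.9 CPM, 2.29, 1.75 to 3.17 over the 2 libraries), Car4 (2.14), Timp4 (2.13), Rbp7 (1.97), Cxcl12 (1.96), Ly6a (1.87), Gbp8 (2.20), Gbp4 (1.84) and Cd36 (1.57). The capillary list had a median of 1.41, above every random list. The interferon response list was high against random lists (0.56, percentile 99.39), with Rsad2 (2.09) called of its 4 measured genes, and stood at 1.06 against replicate 2 alone and 0.24 against replicate 1 alone. Immediate early and dissociation genes lay below every random list (-0.50), with 1 of 16 called, and stood at -0.86 and -0.34 against the same replicates. Progenitor-like fibroblast (0.61) and arterial (0.45) lists were high with 1 member called in each, at 1.16 and 0.86 against replicate 2 alone and 0.22 and 0.33 against replicate 1 alone. Glycolysis was low (-0.19) with no member called, at -0.23 and -0.30. The pan-immune list stood at -6.69 and -4.85, MHC class II at -3.74 and -2.43 and the capillary list at 2.22 and 0.87 against replicates 2 and 1.

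Col1a1 (0.82, 0.09 to 2.39) and Col3a1 (0.75, 0.01 to 2.37) were within a factor of 2 of one cKit+/DDR2- library and higher than the other. The fibrillar matrix (0.49, percentile 99.99) and basement membrane (0.52) lists were high against random lists with no member called, and stood at 0.17 and 0.56 against replicate 2 alone and 0.73 and 0.26 against replicate 1 alone. Vwf (0.05) and Nr2f2 (0.14) were nearly equal. Ddr2 stood at 15.3 against 8.49 CPM (0.78, 0.14 to 1.95), so that it did not reach 2-fold against both libraries, and Kit at -0.33. Within blood endothelial-like cells, 6 of 3241 genes were at least 2-fold apart from both libraries, 73 from replicate 2 alone and 127 from replicate 1 alone, and 22 with classes from single cells. Cd274, the gene of the checkpoint ligand PD-L1 (1.51, 1.40 to 1.62), and Angptl4 (1.28) were higher, and Lyz2, Hsph1 (-2.17), P4ha1 (-1.16) and Ahsa2 (-1.15) lower. The interferon response list (0.57) and the capillary list (0.42) were high, and fibroblast activation (-0.74), fibrillar matrix (-0.55) and glycolysis (-0.23) low, with no member called. Fibrillar matrix turned to 0.092 in the largest shared cluster, where replicate 2 alone was compared. Immediate early (-0.30), venous (-0.33) and arterial genes (0.35) were called too, but stood at 0.080, 0.69 and 0.61 against replicate 1 alone and -0.58, -1.06 and -0.28 against replicate 2 alone. MHC class II genes did not separate the sorts (0.08), because the 2 cKit+/DDR2- libraries lay on either side: the median was -0.76 against replicate 2 and 2.33 against replicate 1. The clusters of the class also differed, since the Apln cluster held 56.6% of it in replicate 1 and 19.9% in replicate 2.

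The comparison of cKit+/DDR2+/CD45+ with cKit+/DDR2+/CD45- asks what the CD45 gate parts within the double-positive cells. The pan-immune and MHC class II lists were higher in cKit+/DDR2+/CD45+. Single genes that were higher included complement C1q genes, the growth factor receptor gene Csf1r and Retnla, a gene of alternatively activated macrophages. The capillary, venous and arterial endothelial lists were lower. The complement and chemokine list, which does not hold the C1q genes, had 3 of its 3 measured genes lower and was not called (-2.97, percentile 2.635). Of 3834 genes, 709 were at least 2-fold higher and 873 lower in cKit+/DDR2+/CD45+.

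Ptprc (318 CPM), Ccl3 (1293 CPM), Retnla (1006 CPM) and Rgs1 (827 CPM) are not listed for cKit+/DDR2+/CD45-. With 2 cells there at the highest mean UMIs of positive cells they would be 361-fold, 429-fold, 153-fold and 306-fold higher, and at the highest UMIs of any cell 79.0-fold, 42.9-fold, 7.33-fold and 24.9-fold. C1qa had 5731 against 5.61 CPM (9.76), C1qc 9.58, Csf1r 9.59, Cxcl2 9.92 and Cd74 6.05. Ccl7 (6.83), Hk2 (4.07), Atf3 (3.16), Igf1 (2.28) and Tgfb1 (1.25) were also higher. The pan-immune list had a median of 7.79 with 10 of 10 genes higher, and the MHC class II list 4.88. Lower were Iigp1 (-5.89), Clu (-5.61), Nrg1 (-5.47), Npr3 (-5.40), Rbp7 (-5.34), Gbp8 (-5.29), Car4 (-5.26) and Fabp4 (274 against 9556 CPM, -5.12). Kit (-2.40) and Ddr2 (-2.79) were both lower in the CD45+ cells, although both gates were applied to them. The capillary (-4.67), venous (-4.75), arterial (-4.57), progenitor-like fibroblast (-4.06), fibroblast activation (-3.87), fibrillar matrix (-3.65), basement membrane (-3.59) and contractile (-1.96) lists were low, and the senescence and secretory list was high (1.35, percentile 98.88). The proliferation list (1.30 over 3 genes, percentile 89.56) was not called.

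Endothelial-like cells of cKit+/DDR2+/CD45+ numbered 362, with a median of 1521 UMIs in the blood type, and 180 of them shared their barcode with a cell of cKit+/DDR2- replicate 1. Within blood endothelial-like cells, 112 genes were at least 2-fold higher and 68 lower, of 3352. The higher ones were led by the abundant macrophage transcripts Lyz2, at least 1493-fold, C1qa (7.94, 7.63 to 11.48 on 3 UMIs), C1qb (7.80, 7.67 to 15.48 on 1 UMI) and Tyrobp, at least 260-fold, in a library of 85.8% macrophage-like cells. Pan-immune (5.19), MHC class II (1.66), basement membrane (0.70) and senescence (0.66) lists were high and venous (-1.06) and capillary (-0.55) lists low, and Iigp1 (-3.01), Tgtp2 (-2.82), Gbp5 (-2.19), Car4 (-1.93) and Vwf (-5.05, -11.00 to -3.21 on 1 UMI) lower. A cluster of low-depth cells (median 1081 UMIs) held 48.1% of the class in cKit+/DDR2+/CD45+ and 15.1% in cKit+/DDR2+/CD45-.

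Macrophage-like cells could be compared between cKit+/DDR2+/CD45+ (3345 cells) and cKit+/DDR2- replicate 2 (527 cells). They differed in 37 of 2946 genes, 16 higher and 21 lower in cKit+/DDR2+/CD45+. The complement receptor gene Vsig4 (66.6 against 14.6 CPM, 2.11), the phospholipase gene Pla2g2d (1.35), Retnla (1.15) and Ms4a7 (1.12) were higher, as were Dbp (1.68), Tmem86a (1.09) and Cirbp (1.05). The interferon-inducible chemokine gene Cxcl10 (-2.47), the heat shock genes Hspa1b (-2.24), Hspa1a (-1.79) and Hspb1 (-1.69), Lars2 (-1.84), AY036118 (-1.91), Phlda1 (-1.60) and Mgp (-1.56) were lower. The immediate early list stood at -0.33, below every random list. The class was made up of different clusters: one led by Cd209f, with Pla2g2d among its leading genes, held 14.3% of it in cKit+/DDR2+/CD45+ and 1.33% in cKit+/DDR2- replicate 2. Ptprc was alike (0.11), and Kit stood at 1.74 against 3.56 CPM. This pair also crosses the Xist split.

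The comparison of cKit+/DDR2- with cKit-/DDR2+ contrasts the cells carrying either marker alone. Over whole libraries, the fibrillar matrix and complement and chemokine lists were lower in cKit+/DDR2-, beside 0.229% and 4.97% of fibroblast-like cells against 39.8%, and the pan-immune and MHC class II lists higher. Single genes that were higher included Ccl21a, Mmrn1, Nrg1 and Npr3. Of 3603 genes, 224 were at least 2-fold higher and 292 lower in both libraries. Replicate 1, which lies on the same side of the Xist split as cKit-/DDR2+, gave 630 genes on its own, and replicate 2 gave 792. Ccl21a (8.67), Mmrn1 (6.45), Reln (6.28), Lyve1 (5.86), H19 (5.85), Nrg1 (5.16), Npr3 (4.88), Smoc1 (4.46) and Vwf (3.90) were higher. Penk (-5.78), Wisp2 (-5.49), Ccl11 (-5.42), Myoc (-5.30), Dpep1 (-5.18), Hsd11b1 (-4.88), Cxcl14 (-4.81), Col1a1 (-4.31, -5.88 to -3.58), Pi16 (-4.31) and Efemp1 (-4.23) were lower. Kit was higher (2.39, 2.00 to 2.69) and Ddr2 lower (-3.49). The pan-immune list (3.81) was above every random list and the MHC class II list (4.81) above nearly every one (percentile 99.995), and the complement and chemokine (-3.72) and fibrillar matrix (-2.75) lists below every one. Venous genes (1.66) were high as well, and progenitor-like fibroblast (-2.38), basement membrane (-2.11), growth factor (-1.60), senescence (-1.56), arterial (-1.54), capillary (-1.20) and immediate early genes (-0.42, percentile 0.83; -0.59 in replicate 1 alone) low. In replicate 1 alone the medians were 2.83 (pan-immune), -4.84 (complement and chemokine) and -2.99 (fibrillar matrix), and Ccl21a stood at 9.30. Penk, Wisp2, Ccl11, Myoc and Dpep1 are not listed for replicate 1 and were set to 0 there.

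Fibroblast-like cells could be compared between cKit+/DDR2- replicate 2 (150 cells) and cKit-/DDR2+ (908 cells), across the Xist split. They differed in 62 of 3207 genes, 25 higher and 37 lower. Heat shock genes (Hspa1b 3.37, Hspa1a 2.57), Lars2 (3.01), AY036118 (2.57), Nr4a2 (2.17) and Igfbp3 (1.57) were higher, as were Ccl21a (6.52, 97.7 CPM against 1 UMI), Ccl4 (5.70, 58.9 CPM against 2 UMIs) and Cd74 (2.49), which belong to other classes of that library. The activation gene Postn (1.29) and Cdkn1a (1.29), a cell cycle inhibitor gene, were higher as well. The complement gene C4b (-4.45, -7.35 to -3.52 on 3 UMIs), the chemokine gene Ccl11 (-1.71), Wisp2 (-3.48), Cd36 (-2.91), Fabp4 (-2.77), Pdlim3 (-2.38), Penk (-2.10), Efemp1 (-1.90), Stc2 (-1.75) and Igf1 (-1.01) were lower. Kit gave 3 UMIs in the 150 cells (1.77 against 0.758 CPM, 0.65), and Ddr2 stood at 183 against 157 CPM (0.22, 0.04 to 0.39), in cells of a gate negative for DDR2. The fibrillar matrix list (0.03, percentile 98.365, 0 of 17 genes called) was above most random lists but turned to -0.012 with totals without mitochondrial, ribosomal and haemoglobin genes. Basement membrane (0.24, 99.87, 0 of 9) and mesenchymal transition factors (0.27, 98.83, 0 of 5) were high too, and complement and chemokines (-0.32, 0.97, 3 of 9 lower) and capillary genes (-2.77, 0.005) low. Progenitor-like fibroblast (-0.07, 55.07), senescence (0.04, 87.35) and growth factor genes (-0.23, 6.515), low over whole libraries, were not called in this class. Cd36 and Fabp4, the capillary genes called, are markers of blood endothelial-like cells. That class made up 51.8% of cKit-/DDR2+ and 10.3% of cKit+/DDR2- replicate 2.

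Within blood endothelial-like cells, 13 genes were at least 2-fold higher and 17 lower in both cKit+/DDR2- libraries, of 3377, with 161 apart in replicate 1 alone and 111 in replicate 2 alone. Lrg1 (5.10), Ccl21a (4.92), Cxcl9 (2.54), Cd74 (3.71, 1.46 to 4.55), Vwf (3.16) and Kit (2.52, 1.19 to 3.20) were higher. Gsn (-4.70), Dcn (-3.52), Ndufa4l2 (-3.04), Cox4i2 (-2.14), Cygb (-2.09), Alpl (-1.85), Igfbp3 (-1.66) and Cxcl12 (-1.39) were lower, and the arterial list stood at -1.31, below every random list. The MHC class II list stood at 3.07 and venous genes at 0.68, the latter at -0.54 in replicate 1 alone. H2-Aa stood at 7.57 CPM in replicate 1 and 97.3 CPM in replicate 2, against 5.56 CPM in cKit-/DDR2+. H2-Ab1 (14.1 and 125 against 7.41 CPM) and Cd74 (29.2 and 256 against 9.94 CPM) went the same way. The higher MHC class II median thus came mostly from replicate 2, which lies across the Xist split. Fibroblast activation (0.57), basement membrane (0.36) and senescence genes (0.30) were high too, but turned to -0.030, -0.27 and -0.30 in replicate 2 alone. With classes from single cells, which took in endocardial-like cells, Dcn turned to 1.52 and 403 genes lay 2-fold apart. As in the double-positive cells, the Apln cluster held more of this class in cKit+/DDR2- than in cKit-/DDR2+.

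The study's title speaks of a youthful phenotype. These libraries can give shares of proliferating cells, and whether such shares reflect that phenotype was not tested. Cells with UMIs of at least 2 of 8 cell cycle genes, after thinning to 1000 UMIs, made up 0.180% of cKit-/DDR2+ (0.049 to 0.459), 0.233% and 0.135% of the cKit+/DDR2- libraries, 0.313% of cKit+/DDR2+/CD45- (4 of 1277 cells) and 0.834% of cKit+/DDR2+/CD45+ (0.564 to 1.19). The binomial intervals of the first 4 libraries overlap at this depth, and a difference between them was not tested. No fibroblast-like cell of cKit-/DDR2+ passed (0 of 908, with a floor of 3 cells at 0.330%), and none of the 40 of cKit+/DDR2+/CD45-, where 3 cells would be 7.50%. In blood endothelial-like cells the shares were 0.675% in cKit+/DDR2+/CD45- (4 of 593 cells) and 0.0880% in cKit-/DDR2+ (1 of 1137 cells). The class was made up of different clusters: that with Apln and Nes held 223 of 636 cells in the former and 64 of 1182 in the latter. Within that cluster Mki67 was seen, without thinning, in 4.48% and 4.69% of cells (10 and 3 cells). Macrophage-like cells gave 0.923% in cKit+/DDR2+/CD45+ and 0.596% in cKit+/DDR2- replicate 2.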

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

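All tests in this part were chosen after the results they address were seen.

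Barcodes recur between 2 libraries, a signal outside the planned comparisons: 190 cell barcodes of cKit+/DDR2+/CD45+ also occur in cKit+/DDR2- replicate 1, against at most 3 in the other 9 library pairs. Of these cells of cKit+/DDR2+/CD45+, 180 are endothelial-like, which is 49.7% of the endothelial-like cells of that library. They hold a median of 622.5 UMIs, and their namesakes 12133.5, with a median share of 5.21% of the namesake's UMIs. Over 1905 genes their profiles correlate at a median of 0.485 with the namesake and 0.282 with other shared cells. Among cells of the same class, the namesake had the higher correlation in 100% of cases, which fits reads of cKit+/DDR2- replicate 1 counted in cKit+/DDR2+/CD45+. Chance reuse of a barcode is argued against because the namesake was the closest of the 190 in 100% of cells. How the reads came to be counted there stays open, and a biological explanation was not tested. Without shared barcodes, 182 endothelial-like cells remain, 4.91% of the cells of cKit+/DDR2+/CD45+.

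Fibroblast-like cells are few in a sort gated on DDR2: 3.01% in cKit+/DDR2+/CD45- against 39.8% in cKit-/DDR2+. An exchange of labels with cKit+/DDR2- replicate 2 is argued against by Ptprc, seen in 26.2% of the cells of that library and not listed for cKit+/DDR2+/CD45-, where a gene not listed may have been seen in up to 2 of 1327 cells. Fibroblast RNA carried by endothelial-like cells, as doublets or attached fragments, stays open. The median log2 of 10 fibroblast markers was 0.90 against replicate 1 of cKit+/DDR2- and -0.18 against replicate 2. This median cannot decide, because it pools blood, endocardial and lymphatic endothelial-like cells, whose shares differ between libraries. The markers also include Dcn, at 1364 CPM in endothelial-like cells of replicate 1, a library with 0.229% of fibroblast-like cells. DDR2 protein on endothelial cells with little mRNA also stays open. Ddr2 in endothelial-like cells of cKit+/DDR2+/CD45- stood at log2 0.85 (0.12 to 2.11) against replicate 1 and 0.29 (-0.13 to 0.81) against replicate 2, with UMIs in 4.23% of 1254 cells. These explanations cannot be told apart with the libraries at hand.

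In blood endothelial-like cells, 3 of 3 measured MHC class II genes and 8 of 10 interferon-inducible GTPase genes were at least 2-fold higher in cKit+/DDR2+/CD45- than in cKit-/DDR2+. The GTPase genes were gathered after Iigp1 and Tgtp2 were seen and were not set against random lists. In both groups only genes with at least 50 CPM in cKit+/DDR2+/CD45- or cKit-/DDR2+ were taken. The MHC class II genes and Gbp3, Gbp5, Igtp, Irgm1 and Tgtp2 passed through cKit+/DDR2+/CD45- alone, so that these counts lean toward higher values there. For MHC class II, macrophage RNA is argued against: the marker RNA seen was 0.355% of the level needed. A shift between clusters is argued against as the sole source, since the lowest cluster median was 1.42, although Cd74 alone was at -0.21 in that cluster. For 10 GTPase genes (median 1.43), the sort on cKit is argued against as the sole source by the medians against cKit-/DDR2+ of the cKit-sorted libraries on the same side of the Xist split (-0.21 in cKit+/DDR2- replicate 1, -0.13 in cKit+/DDR2+/CD45+ without shared barcodes), while replicate 2, on the other side, stood at 0.59 with 10 of 10 genes higher. The sort on cKit was not weighed for MHC class II. A difference between libraries that the sort does not set stays open for both groups. Replicate 2 minus replicate 1 of cKit+/DDR2- had a median of 3.09 for MHC class II in blood endothelial-like cells, beside 3.35 for the pattern itself, but -1.64 in endocardial-like cells, and 1.00 and 1.11 for the GTPases.

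Apoe, Igfbp3 and Trf stood out because their differences between sorts had opposite signs in 2 cell classes. Apoe, a lipid carrier gene, was lower in cKit+/DDR2+/CD45- than in cKit-/DDR2+ in blood endothelial-like cells (-1.05, 251 against 521 CPM) and higher in endocardial-like cells (1.34, 5515 against 2171 CPM), 1 of 2670 genes. In blood endothelial-like cells, cKit+/DDR2- replicates 1 and 2 stood at 263 and 745 CPM, on either side of cKit-/DDR2+. In endocardial-like cells they stood at 8191 and 5671 CPM, both above it. Igfbp3, a growth factor binding protein gene, was higher in cKit+/DDR2- than in cKit-/DDR2+ in fibroblast-like cells (1.57, replicate 2 alone) and lower in blood endothelial-like cells (-1.66, -1.94 to -1.42 over the libraries), 1 of 2420 genes. Trf, the transferrin gene, was lower in fibroblast-like cells in that comparison (-1.09, replicate 2 alone) and higher in endocardial-like cells (1.85, 1.45 to 2.17), 1 of 2478 genes. The difference between the classes was not tested for any of the 3 genes, and no sort has the 4 libraries needed to ask whether a library lies far from the others.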

How the results depend on the processing

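Among the alternatives, 8537 log2 ratios of named genes stayed within their spread of the main value, 1317 moved beyond it and 9 of called genes changed sign. The spread was 0.5 times the width of the 95% interval or, with both cKit+/DDR2- libraries, 1 SD between them, and at least 0.1. That SD is wide, as for Col1a1 in cKit+/DDR2+/CD45- minus cKit+/DDR2- (0.087 and 2.39 with 1 replicate left out). For list medians, with 1 SD of the random lists as spread, the numbers were 2151, 449 and 21. A further 284 ratios and 136 medians that were not called changed sign, within or beyond the spread. Counts of genes at least 2-fold apart stayed within 1.5 times in 138 cases and moved in 53, and counts of called lists in 162 and 29. Shares of cells stayed within their 95% interval, or 1 SD between the cKit+/DDR2- libraries, in 164 cases and moved in 42, counting 2 percentages of genes that were held to 1.5 times. TMM factors, no cell filter, the stricter cell filter, doublet removal, resolutions 0.5 and 2 and totals without Gm42418, AY036118 and Lars2 moved 0 of the 2-fold counts.

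A lower minimum of 10 CPM admits more genes by its construction. It gave 1307 (main 617), 356 (123), 3300 (1582) and 1231 (516) genes in the whole-library comparisons, in the order of the report. It gave 244 (62) in fibroblast-like cells, 243 (80), 49 (6), 894 (180) and 156 (30) in blood endothelial-like cells and 106 (37) in macrophage-like cells. The minimum of 200 CPM gave 217, 29, 434, 178, then 19, then 30, 0, 41 and 11, then 19.

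Leaving out 1 replicate of cKit+/DDR2- also drops the need for both to pass. The counts then ranged from 161 to 347 for cKit+/DDR2+/CD45- minus cKit+/DDR2- and from 630 to 792 for cKit+/DDR2- minus cKit-/DDR2+, and in blood endothelial-like cells from 73 to 127 and from 111 to 161. Some list medians of blood endothelial-like cells changed sign between the 2 settings. For cKit+/DDR2+/CD45- minus cKit+/DDR2- they ranged from -0.58 to 0.080 (immediate early), -0.28 to 0.61 (arterial) and -1.06 to 0.69 (venous). For cKit+/DDR2- minus cKit-/DDR2+ they ranged from -0.27 to 0.80 (basement membrane), -0.54 to 1.41 (venous) and -0.30 to 0.21 (senescence), and fibroblast activation stood at -0.030 without replicate 1. MHC class II genes of endocardial-like cells in cKit+/DDR2+/CD45- minus cKit+/DDR2- ranged from -0.22 to 1.15. The cause was not tested.

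Classes from marker genes of single cells gave 386, 22 and 403 genes in blood endothelial-like cells, against 80, 6 and 30 for cKit+/DDR2+/CD45- minus cKit-/DDR2+, cKit+/DDR2+/CD45- minus cKit+/DDR2- and cKit+/DDR2- minus cKit-/DDR2+. Reversed were ERK feedback (-0.37), Dcn (1.38), Col15a1 (-0.18) and Fosb (0.031) in the first, H2-Aa in cKit+/DDR2+/CD45+ minus cKit+/DDR2+/CD45- (-0.26), and basement membrane (-0.18), senescence (-1.08) and Dcn (1.52) in the last. This alternative leaves out endothelial cells with UMIs of Col1a1, Pdgfra, Ptprc or Tyrobp and does not part endocardial-like cells, which were 496 of its 1176 cells of cKit+/DDR2+/CD45- and 39 of 1112 of cKit-/DDR2+. In the largest shared cluster, chosen after seeing the data, the last 2 counts were 77 and 118. Replicate 1 of cKit+/DDR2- fell out there with 24 cells, and replicate 2 alone gave 73 and 111 in the whole class. Reversed there were Cd74 (-0.21) in the first, fibrillar matrix (0.092) and arterial genes (-0.16) in the second, and basement membrane (-0.091), senescence (-0.44), Hist1h2ap (-1.26) and Tmem176a (-1.25) in the last. The cause was not tested.

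The mean over cells gave 10, 384 and 18 genes in blood endothelial-like cells for cKit+/DDR2+/CD45- minus cKit+/DDR2-, cKit+/DDR2+/CD45+ minus cKit+/DDR2+/CD45- and cKit+/DDR2- minus cKit-/DDR2+, and reversed the venous list in cKit+/DDR2+/CD45- minus cKit-/DDR2+ (-0.059). Adding 10 CPM gave 3 genes in the first of these. Totals without mitochondrial, ribosomal and haemoglobin genes reversed the fibrillar matrix median of fibroblast-like cells (-0.012 against 0.030). The cause was not tested.

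The stricter cell filter moved fibroblast-like cells of cKit-/DDR2+ to 46.1%, blood endothelial-like cells to 43.4% in cKit+/DDR2+/CD45- and 48.4% in cKit-/DDR2+, endocardial-like cells to 44.7% in cKit+/DDR2+/CD45- and 50.8% in cKit+/DDR2-, and macrophage-like cells of cKit+/DDR2+/CD45+ to 74.5%. Endocardial-like cells moved to 3.55% in cKit-/DDR2+ and 6.41% in cKit+/DDR2+/CD45+. The filter gave no value for blood endothelial-like cells of cKit+/DDR2+/CD45+ and endocardial-like cells of cKit-/DDR2+, which fell under 50 cells. It reversed Hist1h2ap in blood endothelial-like cells of cKit+/DDR2- minus cKit-/DDR2+ (-0.20). Macrophage-like cells of cKit+/DDR2+/CD45+ stood at 83.5% with no cell filter, 83.2% without doublets and 87.0% without shared barcodes, where blood endothelial-like cells stood at 40.8% in cKit+/DDR2+/CD45-, 48.1% in cKit-/DDR2+ and 1.78% in cKit+/DDR2+/CD45+, and endocardial-like cells at 1.67% in the last. Endocardial-like cells of cKit-/DDR2+ stood at 3.31% without doublets, 3.20% at resolution 0.5 and 3.25% at resolution 2. MHC class II genes of endocardial-like cells in cKit+/DDR2+/CD45+ minus cKit+/DDR2+/CD45- (0.76) reversed under the stricter filter (-0.52), without doublets (-0.62), at resolution 0.5 (-0.51) and without shared barcodes (-0.55). The cause was not tested. Within endocardial-like cells, the most frequent class, 2.42% of genes lay 2-fold apart between the cKit+/DDR2- libraries, against 8.94% over whole libraries.

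Depth limits the shares of cells with a gene. At 2000 UMIs, Ddr2 was seen in 2.12% of cKit+/DDR2+/CD45-, 10.6% of cKit-/DDR2+, and 0.310% of cKit+/DDR2+/CD45+, Kit in 1.55% of cKit-/DDR2+ and 4.76% of cKit+/DDR2-, Ptprc in 44.5% of cKit+/DDR2+/CD45+, and 0.751% of cKit+/DDR2- were proliferating. Without thinning, Ddr2 stood at 7.08%, 36.1% and 0.949% in these sorts and 4.67% in cKit+/DDR2-. Kit stood at 10.3% in cKit+/DDR2+/CD45-, 3.46% in cKit-/DDR2+, 12.8% in cKit+/DDR2- and 2.87% in cKit+/DDR2+/CD45+, Ptprc at 83.0% in the last, and proliferating cells at 0.482% in cKit-/DDR2+, 1.32% in cKit+/DDR2-, 0.904% in cKit+/DDR2+/CD45- and 3.95% in cKit+/DDR2+/CD45+. More UMIs per cell raise these shares by construction. No paired analysis was possible because the sorts share fewer than 2 replicate numbers.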

Other observations

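Among blood endothelial-like cells Kit was highest in the cluster with Apln, a gene of sprouting capillary tip cells, and Nes, an intermediate filament gene of immature cells. That cluster had Kit at 103 CPM in cKit+/DDR2+/CD45- (39.5% of 223 cells), 197 and 107 CPM in the cKit+/DDR2- libraries and 60.5 CPM in cKit-/DDR2+, while the Rbp7 cluster of cKit+/DDR2+/CD45- had 13.9 CPM. Apln stood at 215 CPM in the former cluster and 5.20 CPM in the latter. Dendritic-like cells of cKit+/DDR2- replicate 2, with Xcr1 in 95.3% and Flt3 in 73.0% of 233 cells, had Kit in 68.2% of cells (85.7 CPM). Cardiomyocyte-like cells of the same library had Kit in 0 of 31 cells, where 3 cells would be 9.68%, and Ptprc in 17 of them.

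With a minimum of 30 cells, chosen after seeing the data, fibroblast-like cells of cKit+/DDR2+/CD45- (40 cells) could be set beside those of cKit-/DDR2+ (908 cells). Of 3295 genes, 32 were at least 2-fold higher and 48 lower. Postn, a matricellular gene of activated fibroblasts (309 against 55.2 CPM, 2.47), the chemokine gene Ccl8 (84.1 against 4.32 CPM), the growth factor gene Ptn (1.70) and the collagen gene Col14a1 (1.66) were higher. So were Lars2 (2.87), AY036118 (2.22) and Hspa1b (2.27), which were also higher in fibroblast-like cells of cKit+/DDR2- replicate 2. Cxcl14 (68.0 against 502 CPM, -2.87), Ccl11 (-3.75), Ccl7 (-4.07), Apod (-2.76) and Penk (-2.53) were lower. Ddr2 stood at 179 against 157 CPM (0.19, -0.12 to 0.48), and Kit had 2 UMIs. The lists of fibrillar matrix (0.22), basement membrane (0.45), immediate early and dissociation (0.17, percentile 99.85) and senescence genes (0.23, 98.83) were high against random lists, capillary endothelial genes low (-2.52), and the progenitor-like list was not called (0.04). Against cKit+/DDR2- replicate 2, on the same side of the Xist split, 17 genes were higher and 28 lower, of 3307. There fibrillar matrix genes were high (0.20, 99.245) and mesenchymal transition factors low (-0.26, 0.92), while basement membrane (0.13, 83.845), immediate early (0.11, 89.015) and senescence genes (0.016, 34.35) lay within the middle 95% of random lists.

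Endocardial-like cells, also added after seeing the data, differed in 153 of 3214 genes between cKit+/DDR2+/CD45- (539 cells) and cKit-/DDR2+ (56 cells), 95 higher and 58 lower. MHC class II genes were higher here too (list median 4.89, H2-Ab1 at 184 against 13.2 CPM), as were Sost (4.17), Irgm2 (3.60) and Edn1 (3.44). The 56 cells of cKit-/DDR2+ hold 530269 UMIs, with H2-Aa at 3.77 and Cd74 at 1.89 CPM, so that these MHC class II folds rest on few counts. H2-Ab1 was also above cKit-/DDR2+ in the cKit+/DDR2- libraries (224 and 99.8 CPM) and in cKit+/DDR2+/CD45+ (320 CPM). Lowest was the red blood cell gene Alas2, not listed against 253 CPM. It would be 70.7-fold lower if 2 cells held the mean of its positive cells in cKit-/DDR2+ (11.0 UMIs). At its highest UMIs in any cell (55) the fold would be 14.1. In cKit-/DDR2+, 46 of the 56 cells, those of the largest cluster, had 0 UMIs of Alas2, so that its level came from the remaining cells. Fam46c (-4.23) followed. Cdkn1a (-3.14), Pthlh (21.5 against 196 CPM, -3.13), Mkrn1 (-2.77), Bpgm (-2.72), another red blood cell gene, Ramp3 (-2.49) and Inhba (-2.33) were lower as well. Against cKit+/DDR2-, 13 of 3114 genes were called. H2-DMa (1.62), Ly6a (1.64), Gbp8 (2.06) and Nuak1 (1.14) were higher, and immediate early genes lay below every random list (-0.72). Between cKit+/DDR2+/CD45+ and cKit+/DDR2+/CD45-, 62 genes were higher and 53 lower, of 3273. A cluster of low depth (median 671 UMIs) held 68.9% of the class in the former and 2.41% in the latter. Between cKit+/DDR2- and cKit-/DDR2+, 52 genes were higher and 44 lower.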
